A study of Solanum tuberosum and Solanum acaule with 12 samples.

How the data were processed

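Shoot explants of the allotetraploid wild potato Solanum acaule and of the autotetraploid potato cultivar Solanum tuberosum cv. Atlantic were compared after freezing and under control conditions, with 12 libraries in 4 groups of 3. In the freezing groups the chamber was cooled from 22 °C to -4 °C at 2 °C per hour, and control plants were kept in long days, per the labels. The labels call the replicates biological and give each group the numbers 1 to 3, so p-values measure the spread between these libraries. RNA was extracted with a column kit and made into stranded mRNA libraries, per the labels' protocols.

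Trimmomatic 0.39 and DESeq2 are named in the submitters' processing notes, with no role given for the latter. The aligner, the assembler, the program that estimated abundance and the genome builds are not given in the sources used here. The authors deposited 1 table per species, with 1 row per assembled transcript and 1 signal value per library. The deposited signal had the form of TPM divided by a TMM library factor: totals ran from 912356 to 1102442 per library, and the geometric mean of the 6 totals of a table was 1000000. This reading comes from the values and the deposited table names. The values are not counts and keep no depth, so sequencing depth is unknown, no counting interval was computed, and precision rests on the replicates. Every value column was matched to a sample by its name, and 0 other columns were left over.

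A placement table per species, deposited without a header, lists for assembled transcripts a gene model, a chromosome with a number and a start and end. For S. acaule it also gives a deposited score from 1 to 40 whose meaning is not stated. 44.8% of its rows had a score of 40 and 54.3% a score of 3 or less. Whether a low score marks a less certain placement is not known. Chromosome names end in 1 or 2 in S. acaule and in 0 to 4 in Atlantic. These are called chromosome sets and chromosome copies here, after the ploidy in the series title, since the tables do not say what the numbers stand for. Coordinates are printed as the tables give them, and the build is not named. Placements covered 71.6% of the 245239 S. acaule transcripts and 88.9% of the 252591 Atlantic transcripts.

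Of the assembled transcripts and gene models, 0 matched the reference table of gene names, so no gene or protein name is printed. The 28 gene lists fixed before the data were examined could not be tested, and neither could the planned difference between the species, which needed proteins shared between the tables. Identifiers of the 2 assemblies have nothing in common, and the tables were normalized separately, so no level and no count of calls was tested across species. Only the freezing effects on 3 library measures were compared between the species, by exact permutation of the labels within each species.

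Values of transcripts with the same assembly number were summed to loci, of which there were 70880 in S. acaule and 60683 in Atlantic. Loci at 1 or more in at least 3 libraries were tested, which left 29331 and 27034. Each species was fitted alone with limma 3.58.1 in R 4.3.3 on log2(signal + 1), with a trend of the variance on the mean, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of low loci. Named loci follow the rule fixed before the data were examined, without its condition on protein names and with fewer loci than it foresaw. It asks for an adjusted p under 0.05, a mean of at least 10 in the higher group and no overlap between groups. Of these loci, the 2 per direction and species with the largest log2 fold change are named. Replicate numbers were not used as pairs, since the deviations of same-numbered libraries did not correlate above 0.1 in every pair. In S. acaule only replicate 3, whose control stood apart, was below that value, at 0.04 against 0.28 and 0.27. The deposited column names give a control and a freezing library of a species the same replicate name. The rule does not show that the libraries were unpaired, so a block for the number was an alternative.

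The analyses of chromosome sets, copies, gene models and neighbouring genes were chosen after the data were seen. For S. acaule, 10211 loci with transcripts on both sets at the same minimum were compared by their log2 ratio within each library. Transcripts placed on a single gene model were summed to gene models. Those that overlapped more than 1, 66844 in Atlantic and 6604 in S. acaule, were left out. Neighbouring gene models called in the same direction were counted against 10000 permutations of the calls, with fewer permutations in the alternatives. Chromosomes were compared by Fisher's exact test over gene models. Gene models are not independent replicates in either test. Tables were read with pandas 2.3.3 and library measures compared by exact permutation tests in scipy 1.17.1.

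The limma step was tested on simulated values for the real loci, with 50 changed loci per fold size. Changes were planted only in loci well above the minimum signal, and each locus had the same simulated spread in every library. At 2-fold, 0% were called for S. acaule and 20.0% for Atlantic. At 4-fold, 70.0% were called for S. acaule and 82.0% for Atlantic, at 8-fold 96.0% and 94.0%, and at 16-fold 90.0% and 98.0%. The simulation gave 135 calls in all for S. acaule and 153 for Atlantic, against 163 and 3535 in the deposited data. The Benjamini-Hochberg adjustment depends on how many loci change. The simulated percentages therefore do not give the share of real changes found in Atlantic. Nor do they give it for S. acaule, where control replicate 3 stood apart, unlike any simulated library. They do not cover loci of low signal in either species. Alternatives covered the pseudocount (0.1 and 5), the filter (none, or at least 5), the scaling (same totals, median-ratio factors, quantiles), the variance trend, a block for the replicate number, rows as deposited, a 2-fold minimum and each library left out. Limma array weights, placed transcripts only, abundant transcripts left out and placements of score 40 only were added after seeing the data.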

Results

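Transcript levels were measured by stranded mRNA sequencing in shoot explants of S. acaule, a wild potato, and of the cultivar Atlantic, after cooling to -4 °C and under control conditions. Each of the 4 groups held 3 biological replicates. Values are scaled TPM signal as described above, and depth is unknown. Between 28279 and 31835 loci reached a signal of 1 in the S. acaule libraries, and between 25501 and 27251 in the Atlantic libraries.

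The first comparison asked which transcripts of S. acaule differ after freezing. Locus AcauleEVm007635 rose from 9.06 ± 1.45 to 298 ± 63.9 (SD, n = 3 per group), a log2 fold change of 4.88 (SE 0.22, limma adjusted p = 0.00297), and the placement table gives no position for it here. Locus AcauleEVm007875, at 43179668 to 43184669 on chromosome 2 of set 1, rose from 7.17 ± 2.59 to 182 ± 21.6 (SD, n = 3 per group; log2 fold change 4.54, SE 0.28, limma adjusted p = 0.0046); it was not called without any one of the freezing replicates (limma adjusted p = 0.0528 to 0.056; 0.00019 to 0.0689 over all alternatives). Locus AcauleEVm016800, at 1023241 to 1024222 on chromosome 3 of set 2, fell from 103 ± 55.5 to 2.67 ± 0.654 (SD, n = 3 per group; log2 fold change -4.64, SE 0.50, limma adjusted p = 0.0252). This call was lost without control replicate 2, without any one of the freezing replicates (limma adjusted p = 0.115 to 0.16) and with no filter on low values (0.0581), with a range of 0.00134 to 0.16 over all alternatives. Locus AcauleEVm021771 fell from 51.5 ± 3.27 to 1.85 ± 0.244 (SD, n = 3 per group; log2 fold change -4.21, SE 0.20, limma adjusted p = 0.00297). It was placed on chromosome 9 of both sets, at 4369187 to 4369894 on set 1 and 4302998 to 4303788 on set 2. With a block for the replicate number none of these named loci was called (limma adjusted p = 0.0684 to 0.121).

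In all, 83 S. acaule loci were higher and 80 lower after freezing, 163 of the 29331 tested by limma, and each of the 163 differed by at least 2-fold. At least 8-fold changes were called for 17 higher and 30 lower loci. Control replicate 3 stood apart from the other libraries, and without it 316 loci were higher and 382 lower; all 163 loci were still called in the same direction. Leaving out any one of the other 5 libraries left far fewer: 42 without control replicate 1, 4 without control replicate 2, and 9, 4 and 8 without freezing replicates 1, 2 and 3. With no filter on low values 44 loci were called, and limma called 0 of the 70329 transcripts tested one by one, with 8307 at an unadjusted p under 0.05. With a block for the replicate number it called 0 loci, with 5104 at an unadjusted p under 0.05, against 4704 without the block.

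**Figure D1:**
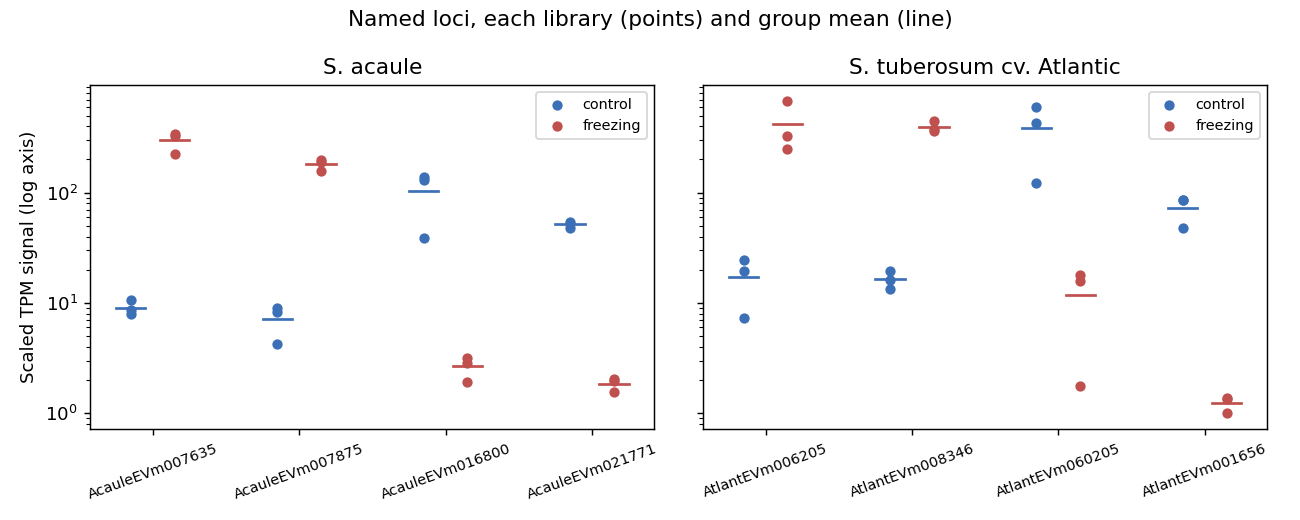
Scaled TPM signal on a log axis of the 4 named loci of each species, with 1 point per library, a line at each group mean, control in blue and freezing in red. The 3 freezing values of AcauleEVm007635 lie between 225 and 343 and its control values between 7.92 and 10.7.

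The chromosome sets of S. acaule differed little in 5 of the 6 libraries and strongly in the sixth. Set 2 held 52.6% to 53.4% of the signal placed on sets 1 and 2 in these 5 libraries and 65.6% in control replicate 3. Over the 10211 loci with copies on both sets, 96.0% of which had both on the same chromosome number, the median log2 ratio of set 1 over set 2 was -1.12 in control replicate 3 and between -0.08 and -0.06 in the others. The shift was present on each of the 12 chromosomes, from -0.74 on chromosome 5 to -1.25 on chromosome 7. The set 2 share was 57.2% ± 7.26 in control and 53.1% ± 0.313 after freezing (SD, n = 3 per group; exact permutation p = 0.7, two-sided, where 0.1 is the smallest p possible; adjusted p = 0.8 over 8 tests of library measures).

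**Figure D2:**
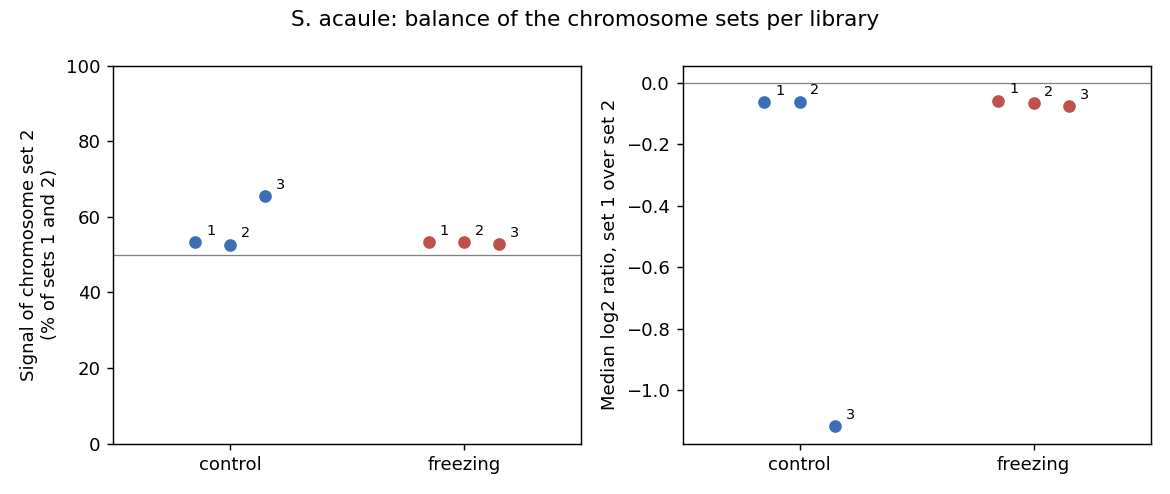
Left, share of chromosome set 2 in the signal of sets 1 and 2 (%), and right, median log2 ratio of set 1 over set 2 across 10211 loci, with 1 point per S. acaule library and its replicate number. Control replicate 3 is at 65.6% and -1.12, away from the other 5 libraries.

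No shift by freezing in the balance between the copies of a locus was called with all libraries, which does not show that the balance was stable. Limma called 0 of the 10211 ratios, with 286 at an unadjusted p under 0.05. Without control replicate 3 it also called 0, but 1386 (13.6%) were at an unadjusted p under 0.05. Of the other 9 splits of these 5 libraries, 1 gave 1555 and another 1378 with 1 ratio called, while the rest gave at most 533. With array weights 1061 ratios were called, but a split that exchanged freezing and control libraries gave 984. Without that library, 71 copies on set 1 and 59 on set 2 were higher and 54 and 42 lower. The 46 loci called on both sets moved in the same direction, but so did nearly all loci among as many top-ranked copies in the other 9 splits of these 5 libraries, with 0 or 1 opposite, so this agreement is not specific to freezing. With all 6 libraries, 3 copies on set 1 and 15 on set 2 were higher and 4 and 16 lower, at 34 loci; 19 such loci were called without control replicate 1 and 0 without any one of control replicate 2 and the 3 freezing replicates. Of 29050 gene models tested, 13 were higher and 22 lower, against 189 and 153 without control replicate 3 and 0 calls without any one of the other 5 libraries (between 1984 and 3647 at an unadjusted p under 0.05 in limma). In each of the 5 libraries without control replicate 3, the set 1 copy was at least 2-fold above the set 2 copy for 1018 loci and the reverse held for 1225. How reads shared between near-identical copies were assigned is not known, which limits these ratios.

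The second comparison asked which transcripts of Atlantic differ after freezing. Locus AtlantEVm006205 rose from 17.2 ± 8.92 to 422 ± 231 (SD, n = 3 per group; log2 fold change 4.55, SE 0.52, limma adjusted p = 0.00735); its transcripts were placed on chromosomes 7 and 8. Locus AtlantEVm008346 rose from 16.4 ± 3.05 to 395 ± 44.9 (SD, n = 3 per group; log2 fold change 4.51, SE 0.18, limma adjusted p = 0.00121) and was placed on copies 1 to 4 of chromosome 2, on copy 1 at 11361676 to 11365622. Locus AtlantEVm060205 fell from 385 ± 244 to 11.8 ± 8.75 (SD, n = 3 per group; log2 fold change -5.05, SE 0.89, limma adjusted p = 0.0187), and was not called without control replicate 1 or 3 (limma adjusted p = 0.0755 and 0.07; 0.00486 to 0.0755 over all alternatives). Locus AtlantEVm001656, with no position in the placement table used here, fell from 73.4 ± 22.0 to 1.24 ± 0.209 (SD, n = 3 per group; log2 fold change -5.01, SE 0.26, limma adjusted p = 0.00185).

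In Atlantic 1227 loci were higher and 2308 lower after freezing, 3535 of the 27034 tested by limma, and 656 higher and 1448 lower loci differed by at least 2-fold. The median log2 change of the called loci was 1.06 for those that rose and -1.12 for those that fell. The count was 575, 846 and 1026 without control replicates 1, 2 and 3 and 1441 without freezing replicate 3, with fewer higher than lower loci each time. The balance depended on the setting: transcripts tested one by one gave 5165 higher and 5209 lower, placed transcripts only 975 and 1343, and the stricter filter 726 and 927. The difference between the species in the number of called loci was not tested.

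**Figure D3:**
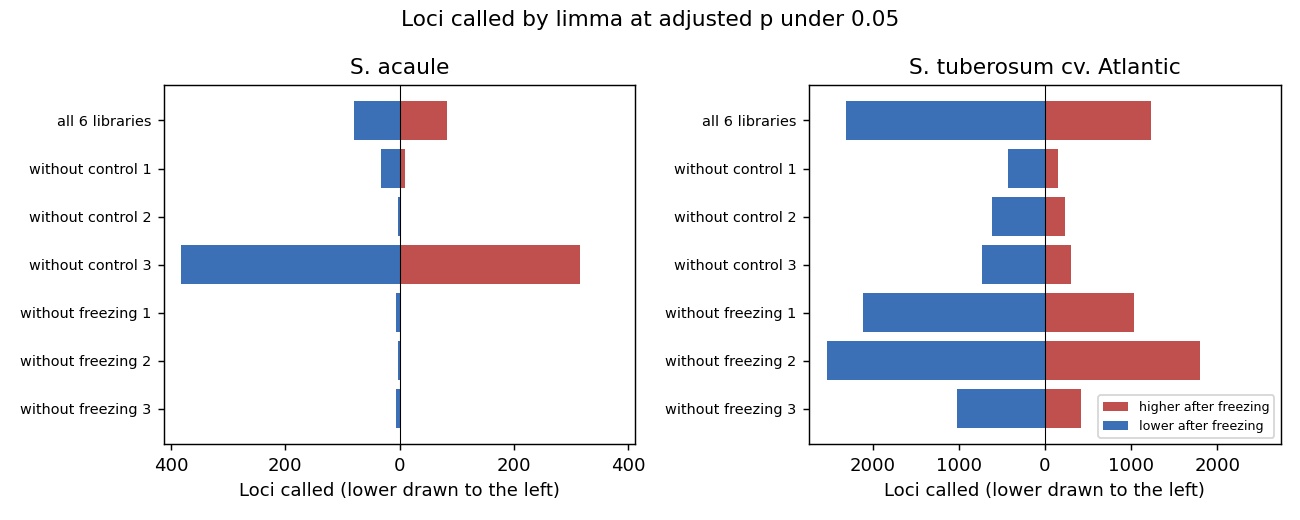
Loci called by limma at an adjusted p under 0.05 (horizontal axis, higher to the right in red and lower to the left in blue; the 2 panels have different scales), with all 6 libraries and with each library left out. S. acaule counts run from 4 to 698 and Atlantic counts from 575 to 4334 when a library is left out.

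Gene models that fell in Atlantic included groups of neighbours on chromosome 2. On copy 2, 5 adjacent tested gene models from 29352533 to 29386690 fell, with a summed signal of 1475 ± 620 in control and 124 ± 76.2 after freezing (SD, n = 3 per group). On copy 4, 5 adjacent gene models from 25775757 to 25799902 fell from a sum of 634 ± 210 to 46.0 ± 27.8, and on copy 3, 3 from 28728503 to 28750006 fell from 1076 ± 348 to 97.1 ± 61.2 (SD, n = 3 per group). The named locus AtlantEVm060205 was placed inside the regions of copies 3 and 4, at 28734573 to 28734767 and 25778790 to 25778984. Gene models are sums of the transcripts placed on them. The fall of this locus and that of the regions can therefore share values and are not independent results. On copy 1 of chromosome 4, 4 adjacent gene models from 23688491 to 23702066 rose from a sum of 11.5 ± 4.92 to 67.8 ± 5.32 (SD, n = 3 per group). Of the 13 gene models of the chromosome 2 groups, only 1, 5 and 2 were still called without control replicates 1, 2 and 3 and 5 without freezing replicate 3. With a block for the replicate number 2 were still called.

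**Figure D4:**
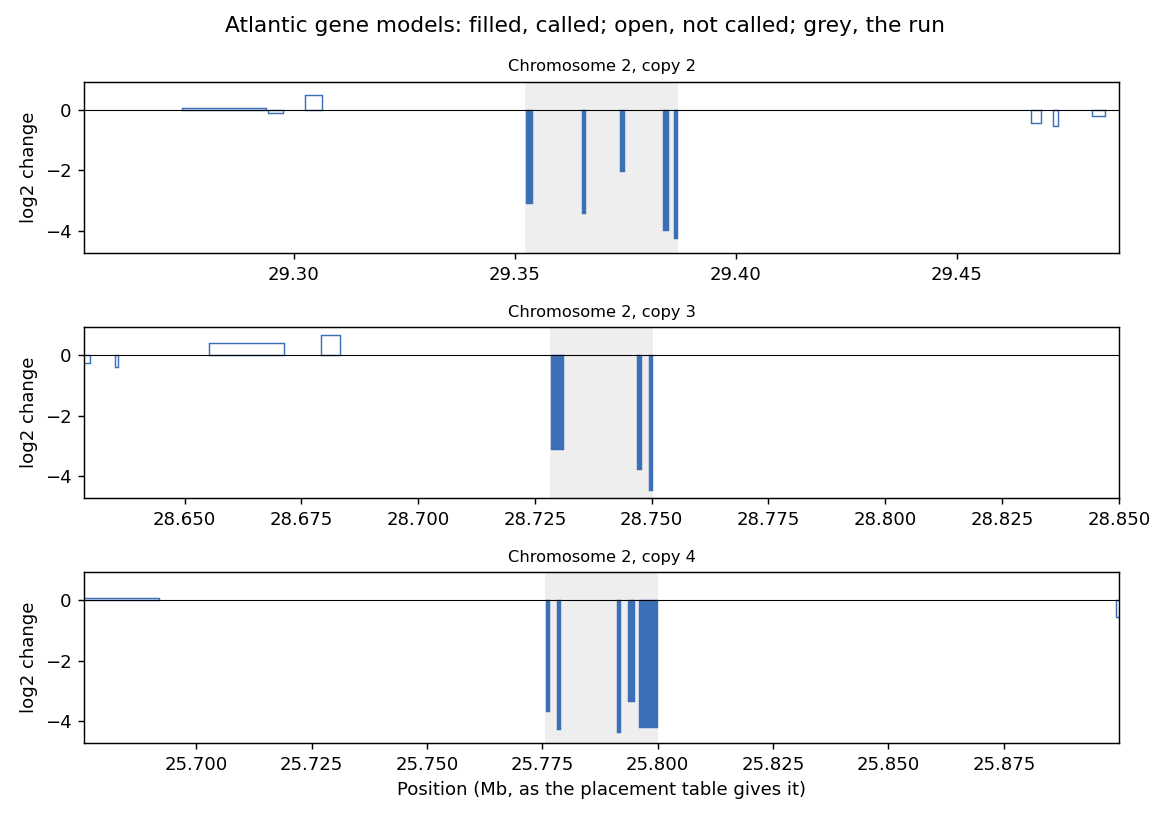
Log2 change after freezing (vertical axis) of Atlantic gene models along chromosome 2 copies 2, 3 and 4 (position in Mb as the placement table gives it), filled where called, open where not, with the groups of neighbours in grey. The 13 gene models in grey were selected as called lower, so all lie below 0.

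Limma called 1203 of the 37846 Atlantic gene models tested as higher and 1471 as lower. The 2674 calls became 227, 300 and 542 without control replicates 1, 2 and 3, 692 without freezing replicate 3 and 4037 without freezing replicate 2. With a block for the replicate number they became 426 (177 higher and 249 lower). The balance turned with the stricter filter (899 higher and 709 lower), without freezing replicate 2 (2083 and 1954) and with array weights (5961 and 4858). Neighbouring gene models were both higher in 75 places, against a mean of 37.2 in 10000 permutations, and both lower in 97 places, against 55.9 (permutation p = 1e-04 each, the smallest these permutations can give). The permutations treat gene models as independent, while the changes of copies of a locus correlated at 0.84 to 0.86. A region can therefore count on several copies, as on chromosome 2, and these p-values overstate the evidence. The ratios to the permuted mean and the alternatives come from a separate set of fewer permutations, whose smallest permutation p is 0.000999. In that set, without control replicate 1 neither excess passed (permutation p = 0.157 and 0.449), at 6.06 and 1.71 times the permuted mean against 1.996 and 1.74 with all libraries. With fewer calls the ratio for higher neighbours was also 6.14 and 6.42 without control replicates 2 and 3 and 5.04 without freezing replicate 3, and that for lower neighbours 4.26, 3.40 and 2.82. Only 79, 108 and 188 gene models were called higher without control replicates 1, 2 and 3, and 300 without freezing replicate 3. The ratios there rest on few calls, so they do not show a larger excess. With more calls it was 1.53 and 1.43 without freezing replicate 2, and 1.15 for each direction with array weights. Chromosome 4 held more risen gene models than the others, 4.50% of 3136 against 3.05% (odds ratio 1.499, Fisher's exact test, two-sided, adjusted p = 0.000577 over 24 tests). No other chromosome and direction passed. The excess on chromosome 4 did not pass the same adjustment without control replicate 1 or 2 or freezing replicate 3, where the odds ratio was no smaller at 1.66, 1.53 and 1.54 (adjusted p = 0.517, 0.628 and 0.0781). These odds ratios rest on the same few higher calls, so they do not show that the excess held. Nor did it pass without freezing replicate 2 or with array weights, where the odds ratio was smaller at 1.22 and 1.078 (adjusted p = 0.132 and 0.329). In S. acaule 13 gene models were called higher, with 1 pair of neighbours against a permuted mean of 0.005 (permutation p = 0.005). Neighbours were both lower in 0 places. Without control replicate 3 there were 5 higher pairs against 1.22 (permutation p = 0.0082) and 2 lower pairs against 0.802 (permutation p = 0.194). These counts are small, and copies are not independent here either. No S. acaule chromosome passed with either set of libraries (Fisher's exact test, lowest adjusted p = 0.214 and 0.498).

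On copies 1 to 4 of the Atlantic chromosomes, 3.30% to 3.61% of locus copies were higher and 4.15% to 4.36% lower, a difference that was not tested. Copy 0 was not among these locus copies, and transcripts placed on more than 1 copy were left out. The latter held 18.8% to 19.7% of the signal of each Atlantic library. How reads shared between near-identical copies were assigned is not known, so the copies may not be independent measurements. Over gene models, 4.50% on copy 0 were lower against 3.78% elsewhere, which did not pass (Fisher's exact test, adjusted p = 0.388). The 2943 called copies became 280, 399 and 571 without control replicates 1, 2 and 3, 803 without freezing replicate 3 and 594 with the replicate block. With the stricter filter 915 were higher and 735 lower. Higher copies also outnumbered lower ones without freezing replicate 2 (2171 and 2167) and with array weights (6207 and 5245). Copy 2 held 51.4% ± 0.141 of the signal of copies 1 and 2 after freezing and 52.3% ± 0.268 in control (SD, n = 3 per group; exact permutation p = 0.1, two-sided, the smallest possible; adjusted p = 0.8 over 8 tests). Of the 562 loci with at least 2 called copies, 0 had copies that moved in opposite directions. Among as many top-ranked copies, the other 9 splits of the 6 libraries gave 0 to 7 such loci out of 459 to 651, so this agreement is not specific to freezing.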

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

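Limma array weights, placed transcripts only and abundant transcripts left out were chosen after seeing the data. The 163 S. acaule loci became 44 with no filter on low values, 0 for rows as deposited (8307 at an unadjusted p under 0.05) and 6694 with array weights, and ran from 4 to 698 with a library left out. With the replicate block they became 0, with 5104 at an unadjusted p under 0.05 against 4704 without it. The 3535 Atlantic loci became 1653 with the stricter filter, 1052 with the replicate block, 2104 with a 2-fold minimum, 10374 for rows as deposited, 2318 with placed transcripts only and 9346 with array weights, and ran from 575 to 4334 with a library left out. The weights came from the same 6 libraries. With them a split that exchanged freezing and control libraries of S. acaule called 4285 loci, so its weighted count was not relied on; in Atlantic the other 9 splits called 0, and whether its weighted count is the better estimate was not tested. The causes of the other shifts were not tested. The other settings kept these locus counts within 1.5 times. The 35 S. acaule gene models became 19 with a pseudocount of 0.1, 20 with no filter, 0 with the block (3776 unadjusted, against 3587 without it) and 3584 with array weights. The 2674 Atlantic gene models became 1608 with the stricter filter, 1597 with a 2-fold minimum, 426 with the block and 10819 with array weights, and the 2943 locus copies 1650, 1614, 594 and 11452. The block left 2 of the 13 gene models of the chromosome 2 groups and raised the neighbour ratios to 8.19 and 5.69, on fewer calls. It ended the call of the chromosome 4 excess. The odds ratio rose to 1.87 (Fisher's exact test, adjusted p = 0.0974), but on only 177 gene models called higher. All 4 named S. acaule loci also lost their call (limma adjusted p = 0.0684 to 0.121), with unchanged log2 fold changes. The direction of the 8 named loci held under all alternatives, but AcauleEVm016800 missed the threshold under 6 of 16, AcauleEVm007875 under 4, AtlantEVm060205 under 3 and AcauleEVm007635 and AcauleEVm021771 under 1 each. The copy ratio count stayed at 0 except for 1061 with array weights. Whether the replicate numbers pair the libraries could not be decided. Same-numbered deviations correlated at 0.28, 0.27 and 0.04 in S. acaule and 0.08, -0.23 and 0.05 in Atlantic. In S. acaule control replicates 1 and 2 correlated best with the freezing library of their own number, and in Atlantic no control did. Control replicate 3 of S. acaule, which stood apart, weighs on the correlations there. The counts with the block therefore stay possible. Alternatives on shared proteins, gene lists and count tests were not run, for want of names and counts. Depth is unknown, so what it limits could not be assessed.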

Other observations

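The tests in this part were chosen after the data were seen, apart from the counts with a library left out and those with rescaling to one total alone. Fold changes of the copies on both sets of S. acaule correlated across loci at 0.44, and at 0.78 without control replicate 3. In Atlantic the same correlation between copies was 0.84 to 0.86. The highest value of any other split was 0.29 for the 6 S. acaule libraries, 0.79 without control replicate 3 and up to 0.87 in Atlantic, so only the first lay above all other splits. The last 2 kinds of correlation also arise without the contrast of freezing and control. Loci are not independent replicates. The freezing effect did not pass a test of its difference between the species for any of 3 library measures (n = 3 per group). For the share without a placement it was 2.30 points in S. acaule and 1.49 in Atlantic (exact permutation p = 0.92). For the loci at 1 or more it was -905 and -506 (exact permutation p = 0.755). For the share of the top 10 transcripts it was 2.81 and 0.75 points (exact permutation p = 0.805). Control replicate 3 had the lowest of these shares among the S. acaule libraries, at 19.6% and 3.97%, and the most loci, at 31835. The S. acaule effects therefore rest largely on that library, and the tests were not repeated without it.

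S. acaule control replicate 3 differed from the other 5 libraries beyond its group. A single scaling factor cancels in a ratio within a library, so the authors' scaling is argued against by the median log2 ratio of -1.12. Low depth, which would scatter low values, is argued against by the 203 loci whose copies both had a mean of at least 100 in the other 5 libraries: their median log2 ratio was -1.15 in it and between -0.02 and 0.04 in the others. A mixture dominated by the labelled plant is argued against by 327 loci absent from it alone, against 0 or 1 elsewhere. RNA from a plant of another genotype, through a wrong label or another accession, may account for these values, since 1278 loci were also present in it alone, against at most 3 elsewhere; no biological explanation was tested, and no sequence was at hand to decide.

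Fewer loci were called in S. acaule than in Atlantic, a difference that was not tested. Control replicate 3 may contribute, since the 698 S. acaule loci called without it lie within the 575 to 1026 that Atlantic gave without 1 control. A group of 9 abundant transcripts without a placement held 10.1% to 24.4% of the signal in 5 S. acaule libraries and 0.0627% in control replicate 3, but leaving them out and rescaling to one total gave 181 calls (91 higher and 90 lower), against 135 (63 and 72) with that rescaling alone, which argues against their effect on the scale as the main cause. A difference between the species stays open, and where these transcripts come from could not be told without sequence.

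Atlantic freezing replicate 2 held 22 transcripts without a placement that were at least 5-fold above every other Atlantic library and made up 3.14% of its signal. With them left out and the rest rescaled to one total, 3151 loci were called (900 higher and 2251 lower), against 3064 (825 and 2239) with that rescaling alone and 3535 (1227 and 2308) as reported. This argues against a large effect of these transcripts on the count; the lower share of risen loci came with the rescaling, whether or not they were left out.

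For each count of calls, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 163 loci, 35 gene models and 7 and 31 copies on sets 1 and 2 in S. acaule, and 3535 loci, 2674 gene models and 2943 locus copies in Atlantic; the highest other split called 0 in each case, so 1 of 10 splits reached the real count. For the copy ratio all 10 splits called 0.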
